A study of Danio rerio with 4 samples.

How the data were processed

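The data are from 4 arrays of zebrafish embryos read in 2 colours, each with klf4-MO RNA in one channel and STD-MO RNA in the other. Per the labels, total RNA was amplified and labelled indirectly with Cy5 and Cy3, and the dyes of arrays 1a and 1b are the other way round from those of arrays 2 and 4. The scanner files hold spot intensity, and per the file headers they are ImaGene output with the red and the green image combined, as foreground and local background medians that are neither background-subtracted nor normalised. The authors' value table holds 1 log2 value per probe and array. How the authors made it is not given in the sources used here, so its background correction, normalisation and averaging of spots stay unknown.

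The scanner file given for array 1a is byte for byte that of array 2, and its header names the slide in the title of array 2. It was therefore used once, for array 2, and 3 scanner arrays remain, 1 for each numbered pair. The value table fills the gap for array 1a: its column for array 1a correlates at -0.489 with that for array 2 before signs are turned, so it is no copy. The plan fixed before the data were examined had taken all 4 arrays from scanner files and averaged the 2 arrays of pair 1. Here that average could be made only in the value table.

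The value table's numbered rows follow the order of printing, once 2 control names are set aside. Every pair of control names was tried, and the pair that gave the highest mean correlation with the scanner values (Blank and ssDNA, 0.9226) was taken. The next pair, Pooled Control and ssDNA, gave 0.9218, so some rows may carry the name of a neighbouring probe. With the pair taken, the table correlated with log2 red over green at 0.965 on array 2, 0.866 on array 1b and 0.937 on array 4. The slopes were 0.935, 0.801 and 0.903. The choice maximised these correlations, so they are no separate check of it. All 33 windows of up to 500 rows lined up best with no shift on each of these arrays, and a shift by 1 row gave 0.0082, 0.036 and 0.076. Windows of this size could miss a shift over a few rows. The table is thus on a log2 red over green scale, for array 1a by the same column format only. Its column medians are 0.00864 on array 1a, 0.00338 on array 2, 0.00585 on array 1b and 0.00687 on array 4.

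Analysis was done in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Background was corrected with normexp (offset 50), and each array was normalised by global loess, with control and flagged spots at weight 0. Flagged spots were then dropped, signs were turned to klf4-MO over STD-MO, and spots of 1 probe were averaged. A probe was tested if it was no control, had an unflagged spot on each of the 3 scanner arrays, and had a foreground over local background plus 2 background SDs in at least 1 channel on all 3. Of 16178 probes, 3245 lacked an unflagged spot on some array and 7 more were too dim, which left 12926. An intercept was fitted to the 3 arrays with weights of 2 for pair 1 and 1 each for pairs 2 and 4, which gives both dye orientations the same total weight. It was followed by eBayes without a trend and Benjamini-Hochberg adjustment at 0.05. The weights were planned for an average of 2 arrays, and here pair 1 is array 1b alone. The fit therefore treats array 1b as more precise than arrays 2 and 4, and its standard errors and adjusted p rest on that. Values from the table use the same 12926 probes.

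Precision was read from probes printed in 2 or more spots. The median SD of the log2 ratio between spots of 1 probe was 0.121 on array 2 over 117 probes, 0.102 on array 1b over 107 and 0.171 on array 4 over 107. The fit was tested on simulated data with 200 changed probes among 12926, drawn from the fitted spread. With the 3 scanner arrays it recovered 37 of 100 changes of 1 log2 unit and 95 of 100 changes of 2 log2 units, with 5 false calls. With the 4 arrays of the value table as independent replicates it recovered 92 of 100 and 98 of 100, with 10 false calls. The simulated noise was independent between probes and equal in spread on every array. The real arrays differed in spread, with an SD in the value table of 0.39 on array 2 and 0.221 on array 1b. The recovered and false counts may therefore not hold for them. Raising the klf4-MO channel of probes 4-fold in the scanner values moved their ratio by a median of 1.84, and lowering it 4-fold moved it by -1.67.

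Levels per channel were taken after loess and Aquantile scaling, and random lists were matched in 20 bins of mean level. Alternatives covered background correction, normalisation, filters, flags, the source of values, weights, a dye coefficient, eBayes settings and leaving out each pair or array. The rule fixed for named genes needs gene names. In its place, chosen after the data were seen, the report identifies the 2 probes with the largest rise in the scanner fit, and the only 2 that fell, among those past the threshold with 1 direction on all 4 arrays. The rank of the rises is not exact: in the value table CGENXEB_456003774_0 had a mean of 1.84, below 1.94 and 1.88 for 2 other probes, the latter with 2 saturated readings. Reference tables of the GRCz12tu assembly matched 1 probe name. The planned gene-level counts, the klf4 transcript and the gene lists fixed in advance were therefore not tested, and no genome positions are given.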

Results

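Gene expression was compared in zebrafish (Danio rerio) embryos given a morpholino against klf4 (klf4-MO) and in embryos given the morpholino labelled STD-MO. A morpholino is a synthetic antisense oligonucleotide that blocks translation or splicing of its target RNA, and klf4 encodes a Krüppel-like zinc finger transcription factor. Each of the 4 samples is a 2-colour array on which amplified RNA of both kinds of embryo was hybridised together, 1 labelled with Cy5 (red) and the other with Cy3 (green). The titles number the RNA pairs 1, 2, 1 and 4 and carry the tag 18S. Below, the arrays are called 1a, 2, 1b and 4, in the order of the series. STD-MO was red on arrays 1a and 1b, and klf4-MO was red on arrays 2 and 4. All ratios are log2 of klf4-MO over STD-MO, so a positive value means a higher level in klf4-MO embryos. Nothing in the labels says whether the pairs came from separate clutches, so p-values measure only the spread between these arrays, which may be technical.

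Scanner intensities of their own were used for arrays 2, 1b and 4, and array 1a entered through the authors' value table alone. Each array carried 16896 spots, of which 16340 held 16178 different probes. On array 2 the median probe spot was 4.2 times its local background in red and 4.90 times in green. The corresponding values were 3.72 and 4.70 on array 1b, and 4.08 and 3.17 on array 4. Flags removed 7.46% of the spots on array 2, 7.70% on array 1b and 14.7% on array 4. The number of arrays limits the precision of every value below.

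The series asks which transcripts differ between klf4-MO and STD-MO embryos. A small group of probes differed strongly and in the same direction on every array. Of 12926 probes tested, 22 were at least 2-fold higher in klf4-MO embryos on all 3 scanner arrays and 6 were at least 2-fold lower. If the arrays were independent and every probe equally likely to change, 0.0028 and 0.0036 probes would be expected. Probes that vary more would pass on several arrays together, so these expected counts may be too low. With the signs of arrays turned, at most 1 probe was at least 2-fold changed on all 3 scanner arrays. All 28 had the same sign on array 1a, and 23 of them were at least 2-fold changed there too. In the limma fit, 10 probes passed an adjusted p of 0.05, with 8 higher and 2 lower in klf4-MO embryos. These 10 are among the 28, had the same direction on all 4 arrays and changed by 1.3 to 2.35 on the log2 scale in size. The largest fall among the 28, a mean log2 ratio of -3.4 over the scanner arrays, was not past the threshold. In the value table, calls reached 3.56 in size, with pair 1 averaged and also with 4 independent arrays. With equal weights for the 3 scanner arrays, in place of a double weight for array 1b, 4 probes passed, 4 higher and 0 lower, and both probes called lower with the planned weights had an adjusted p of 0.0517 in limma. The count was 0 without pair 1, 0 without pair 4 and 49 without pair 2, in fits of 2 arrays that leave 1 residual degree of freedom. Why these counts differ was not tested. The count was also 0 when the fit on the 3 scanner arrays held a dye coefficient. In the value table it was 18 (14 higher and 4 lower) with pair 1 averaged. It was 59 (38 higher and 21 lower) with the 4 arrays taken as independent replicates, although arrays 1a and 1b share a pair number.

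The files give probe numbers without gene names, so only 4 of these probes are identified, by number. Probe CGENXEB_456015047_0 was 5.10-fold higher in klf4-MO embryos, with a log2 ratio of 2.35 (SE 0.155, adjusted p = 0.031 in limma). Its ratios were 2.68 on array 2, 2.39 on array 1b and 1.93 on array 4, a mean of 2.33 ± 0.378 (SD, n = 3), and the value table gave 2.46 on array 1a. Probe CGENXEB_456003774_0 was 4.73-fold higher, with a log2 ratio of 2.24 (SE 0.119, adjusted p = 0.031). Its mean was 2.25 ± 0.173 (SD, n = 3) over the scanner arrays, and its value on array 1a was 1.59. Probe CGENXEB_456011738_0 was 3.19-fold lower, with a log2 ratio of -1.67 (SE 0.142, adjusted p = 0.0493). Its mean was -1.72 ± 0.294 (SD, n = 3), and its value on array 1a was -1.03. Probe CGENXEB_456000794_0, printed in 2 spots, was 2.80-fold lower, with a log2 ratio of -1.49 (SE 0.117, adjusted p = 0.0474). Its mean was -1.46 ± 0.146 (SD, n = 3), and its value on array 1a was -1.43. A channel was saturated in 1 of its spot readings, so this fold and its error are approximate. Each of the 4 kept its direction under all 25 alternatives, which follows largely from their choice for 1 direction on all 4 arrays. Each lost its place past the threshold under 7 to 12 of the alternatives.

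**Figure D1:**
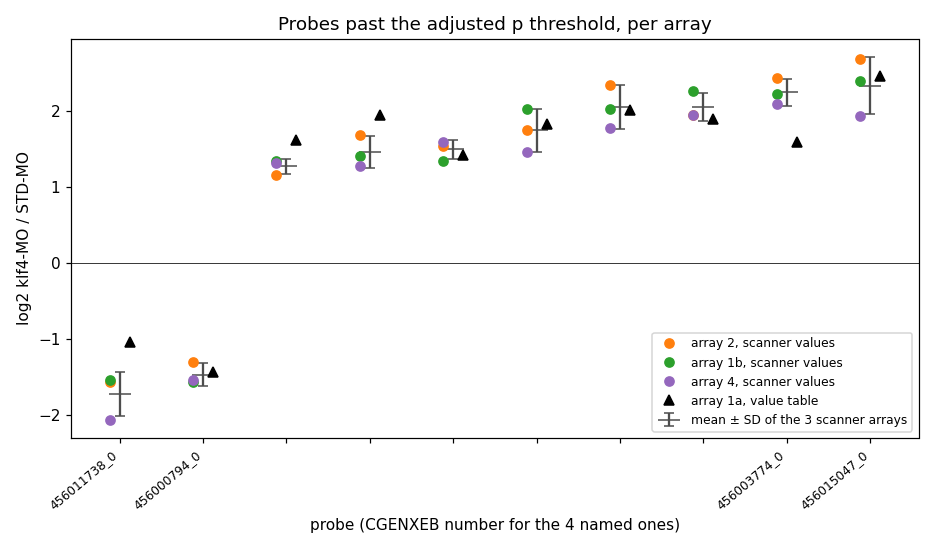
Log2 ratio of klf4-MO over STD-MO (vertical axis) for the 10 probes past the adjusted p threshold (horizontal axis, the 4 identified probes marked by number), with 1 circle per scanner array, a triangle for array 1a from the authors' value table, and bars for the mean ± SD of the 3 scanner arrays. The 8 higher probes lie above 0 and the 2 lower ones below 0 on every array.

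Of the 16178 probe names, 1 is an accession that the reference tables resolve: rarga, which encodes a retinoic acid receptor, a nuclear receptor that binds retinoic acid. It was not past the threshold (adjusted p = 0.999 in limma). Its log2 ratio was -0.76 on array 2, -0.04 on array 1b and 0.90 on array 4, a mean of 0.034 ± 0.835 (SD, n = 3). The value table gave -0.60 on array 1a. The arrays therefore differed in sign for this gene, and the mean is far smaller than the spread between them. The level of the klf4 transcript is not analysed here, because no probe could be tied to it.

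Agreement between the arrays was measured across the 12926 tested probes, which are not independent replicates. On the scanner values Pearson's r was 0.0956 between arrays 2 and 1b (Spearman's rho -0.0118), 0.167 between arrays 2 and 4 (rho 0.273) and -0.0229 between arrays 1b and 4 (rho -0.121). In the value table r was 0.539 between arrays 1a and 2, whose dyes are the other way round, although rho was only 0.217. Arrays 1a and 1b, which share a pair number and a dye orientation, had an r of 0.561 and a rho of 0.581. Array 1a against array 4 gave an r of -0.0575 (rho -0.168).

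The relation between arrays 1a and 2 went with a group of probes lower in klf4-MO embryos on those 2 arrays. In the value table, 211 of the tested probes were at least 2-fold lower on array 1a. Of these, 154 were also at least 2-fold lower on array 2, against 6.37 expected for independent arrays and equally variable probes. On array 1b 8 of them were that much lower, and on array 4 it was 7. Their median log2 ratio on the scanner values was -1.43 on array 2, -0.17 on array 1b and 0.19 on array 4. The 95% intervals from a bootstrap over the probes were -1.55 to -1.29, -0.21 to -0.13 and 0.12 to 0.26. They measure spread between probes, not between hybridisations. Lists of as many probes matched on level gave medians between -0.07 and 0.04 on array 2 in 95% of 10000 draws. These ranges were -0.02 to 0.04 on array 1b and -0.03 to 0.06 on array 4. The median of the set thus lay below the lists on array 1b and above them on array 4. Array 1b shares a dye orientation and a pair number with array 1a, where the set was picked, and array 4 shares neither. Of the 211 probes, 2 are among the 10 past the threshold.

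**Figure D2:**
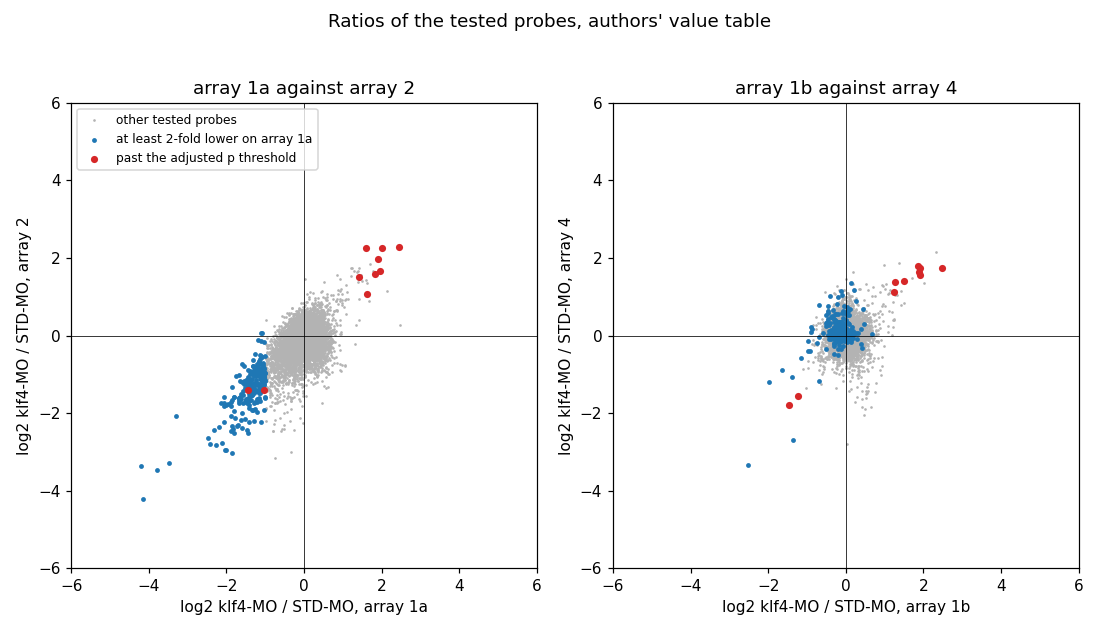
Log2 ratio of klf4-MO over STD-MO in the authors' value table for 12926 tested probes, array 1a against array 2 (left) and array 1b against array 4 (right), with 1 point per probe. The 211 probes at least 2-fold lower on array 1a (blue, or red for the 2 of them past the threshold) lie mostly below 0 on array 2. Their medians were -0.17 on array 1b, with 163 below 0, and 0.123 on array 4, with 61 below 0. The 10 probes past the threshold (red) lie on the same side of 0 on all 4 arrays.

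The level of these 211 probes in each labelled RNA differed between arrays as well as between the channels of array 2. After loess and scaling of the arrays to common intensity quantiles, their median log2 level was 11.76 in the STD-MO channel and 10.26 in the klf4-MO channel of array 2. It was 12.02 in STD-MO and 11.79 in klf4-MO on array 1b. On array 4 it was 9.34 in STD-MO and 9.54 in klf4-MO. Medians of the matched lists lay between 10.67 and 10.90 in the 6 channels. The lists were matched on the mean of these 6 channels, so only differences between channels are informative.

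**Figure D3:**
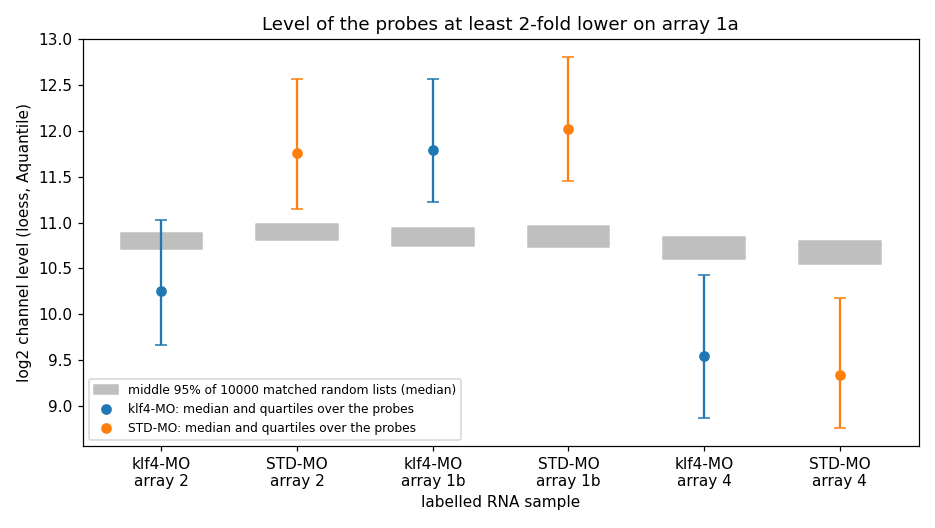
Median log2 level (vertical axis) of the 211 probes at least 2-fold lower on array 1a, in each of the 6 labelled RNA samples of the scanner arrays (horizontal axis), with bars for the quartiles over the probes and grey boxes for the middle 95% of the medians of 10000 matched random lists. Both channels of array 1b and the STD-MO channel of array 2 lie above the grey boxes, and both channels of array 4 and the klf4-MO channel of array 2 lie below them. The lists were matched on the mean of the same 6 channels, so departures above and below must roughly cancel.

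The dye swap addresses how far a dye effect remains. By the titles no pair was hybridised in both orientations, so the dye term is also pair 1 against pairs 2 and 4, and the fit takes arrays 1a and 1b as separate replicates. With a term for the dye and a term for the morpholino on the 4 arrays of the value table, limma gave 0 probes with a dye effect at an adjusted p of 0.05, and 2111 at an unadjusted p under 0.05, against 646.3 expected. The term for the morpholino gave 29 probes in that fit, 17 higher and 12 lower in klf4-MO embryos, and all 10 probes of the scanner fit are among them.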

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

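Probe CGENXEB_456000794_0, which was lower in klf4-MO embryos, had 1 array apart from the rest in the value table: -1.79 on array 4 against -1.40 to -1.46 on the other 3, a gap of 0.853 of the whole range. On the scanner values array 4 did not stand apart, with -1.296 on array 2, -1.56 on array 1b and -1.535 on array 4. The gap in the value table was 1 of 7 values checked over 4 arrays, and chance gives such a gap in about 1 in 20 groups.

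Spots named Blank, which enter no comparison, were above local background more often on array 4 than elsewhere. There 184 of 262 passed the detection rule in at least 1 channel, against 31 on array 2 and 23 on array 1b. Their median red foreground on array 4 was 301.5 over a local background of 169. With detection set instead at the 95th percentile of the Blank spots of each array, an alternative chosen after the data were seen, 21 probes passed the threshold, 17 higher and 4 lower in klf4-MO embryos, and all 10 of the reported probes were among them.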

How the results depend on the processing

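The count of probes past the threshold depended strongly on the processing. The direction of the 4 identified probes could hardly turn, because they were chosen for 1 direction on all 4 arrays and the alternatives reuse these arrays. The 4 identified probes kept their sign under all 25 alternatives, with log2 ratios of 2.15 to 2.52, 1.71 to 2.38, -1.81 to -1.23 and -1.59 to -1.31 in the order of the report, while their adjusted p ran from 0.000131 to 0.541. The counts at least 2-fold changed on every array ran from 17 to 23 higher and from 5 to 7 lower over 4 alternatives chosen after the data were seen. Against 10 probes past the threshold, the count was 16 with no background subtraction, 0 with plain background subtraction (smallest adjusted p 0.0571), 0 with normexp at offset 0 (0.0528), 6 with print-tip loess, 21 when both channels had to be above background on all arrays, and 2 with all spots kept whatever their flag. It was 4 with equal weights (4 higher, 0 lower), 0 with a dye coefficient on the 3 scanner arrays (1 residual degree of freedom; 548 at an unadjusted p under 0.05), and 20 with an intensity trend and robust eBayes. In the value table it was 18 with pair 1 averaged (14 higher, 4 lower), 59 with 4 independent arrays and 29 with these and a dye coefficient. Of the settings added after seeing the data, the Blank percentile gave 21, scaling the log ratios between arrays gave 0 (smallest adjusted p 0.054), and the value table without array 1a gave 14. Leaving out a pair of the scanner arrays gave 0 to 49. In the fit of 4 independent arrays, the count was 14 without array 1a, 9 without array 2, 4 without array 1b and 30 without array 4. All 10 probes were shared in each setting of the value table that kept all 4 arrays. The cause was not tested for any of these settings. With median centring only, 9 probes passed, 5 of them among the 10, the adjusted p of CGENXEB_456000794_0 was 0.32, and r moved to -0.129 between arrays 2 and 1b, 0.51 between arrays 2 and 4 and -0.311 between arrays 1b and 4, and this alternative leaves intensity trends in place by construction. The dye effect gave 0 probes in both scanner alternatives (572 and 622 at an unadjusted p under 0.05), which with 1 residual degree of freedom says nothing about its stability. The pair number as a replicate block was not run, because limma estimates no correlation from 3 blocks among 4 arrays, and alternatives of the gene-level results were not run for want of gene names. Signal over background was lowest in green on array 4, at 3.17.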

Other observations

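Tests of the 211 probes lower on array 1a, of the shared pair number and of the sign patterns of 2-fold changes were chosen after the values were seen. Those of the sign patterns of calls were chosen before their counts were known.

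Most of the 211 probes at least 2-fold lower in klf4-MO embryos on array 1a were not lower to that extent on arrays 1b and 4: 5 were on all 4 arrays, and 2 of these are among the 10 past the threshold. A dye bias as the whole cause would turn their sign on array 2, where the median was -1.43. A smaller dye part stays open, because the medians on arrays 1b and 4, of opposite orientation, differed in sign. A printing or position effect would act on both channels of a spot, and a local one would gather in blocks. The 4 fullest of 32 blocks held 22.7% of the set, below the 25.6% at the upper end of the middle 95% of matched lists. This bears only on effects that gather in blocks, and a printing effect spread over the blocks was not tested. A loss of klf4 with as large an effect in every klf4-MO sample as on array 2 is argued against by array 1b. There the median of the whole set was -0.168 at a level of 12.02 in STD-MO. That median was still below the -0.0224 to 0.0437 of matched lists. This cannot be read as a remaining effect of klf4. The set was picked on array 1a, which shares a dye orientation and a pair number with array 1b. The median of 0.186 on array 4 does not decide, because the level there was only 9.34 in STD-MO and 9.54 in klf4-MO. Whether a further fall can show at such a level was not tested, although 7 of the set were at least 2-fold lower on array 4. A difference between RNA samples that does not follow the morpholino, such as stage or clutch, is a candidate that these values cannot decide. By the titles arrays 1a and 1b share a pair, so it could set them apart only if they held separate samples. The median level of the set was compared between the STD-MO sample of array 4 and the klf4-MO sample of array 1b. Relative to matched lists, the former minus the latter was -2.29 on the log2 scale. Neither of these arrays had a median ratio as low as arrays 1a and 2, so this shows only that the level varied between arrays. That comparison runs across slides, so a slide effect on both channels stays open, as does a stronger knockdown in some pairs. Neither was tested.

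Arrays 1a and 1b carry the same pair number and the same dye orientation, and their ratios had a rho of 0.581 in the value table. The next highest rho was 0.272 between arrays 2 and 4, which also share an orientation but no pair number. By Pearson's r, arrays 1a and 2, which share neither, were almost as close (0.539) as arrays 1a and 1b (0.561). Yet over the 390 probes at least 2-fold lower on array 2, the median ratio was -0.83 on array 1a and -0.06 on array 1b. The median difference was 0.761 (95% interval from a bootstrap over the probes 0.694 to 0.834). That interval measures spread between probes, not between hybridisations. The medians of 10000 random lists of as many probes matched on level were at most 0.0457. This argues against the same 2 amplified RNA samples on both arrays, and it is consistent with a wrong pair number in 1 title, with separate samples under 1 number or with separate amplifications of 1 extract, which these data do not separate. If all 4 arrays held separate pairs, the fit of 4 independent arrays would apply. It would not apply if arrays 1a and 2 held RNA of 1 pair, which was not tested.

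Turning the sign of arrays gives other groupings of the same data. The 3 scanner arrays have 4 sign patterns and the 4 arrays of the value table have 8, too few for a share under 0.05, and in each case only 1 pattern, the real one, reached the real count. The real pattern gave 10 probes past the threshold against at most 0 in the others on the scanner values, and 59 against at most 0 in the value table. For probes at least 2-fold changed on every array, the counts were 28 against at most 1, and 22 against at most 0 in the value table.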
